A study of Homo sapiens with 6 samples.

How the data were processed

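RNA was measured in MCF10A cells transfected with a mimic of miR-221 and miR-222 or a control microRNA, with 3 biological replicates per group per the labels' protocols. Total RNA was biotin-labelled and hybridised to 1 single-colour Affymetrix array per replicate. The deposited values are log2 intensities, normalized across arrays by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA subtracts background, normalizes the arrays to each other and combines the probes of a probe set into 1 value; its version and settings are not given in the sources used here. The log2 scale was read from the values, which run from about 4 to 15 on every array. RMA makes the arrays' distributions alike, so a change in total messenger RNA per cell would not show, and it compresses differences between dim values. The dose, the time after transfection and the sequence of the control microRNA are not given in the sources used here.

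The table holds 54675 probe sets with 0 missing values. The 62 control probe sets were left out, which left 54613 for testing. Gene symbols came from the platform annotation: 41091 probe sets had exactly 1 symbol, 1801 listed several genes and named none here, and 11721 were without a gene name here. Among all probe sets with 1 symbol, control probe sets included, the Entrez identifiers of 41043 matched the reference gene table, 54 did not, and 0 symbols were updated. Each of the 19775 genes was read at the probe set with the highest mean over all 6 arrays. Of the 10523 genes with more than 1 probe set, 114 had 1 probe set called higher and another lower, 90 had another probe set called against the one used, and for 1333 the one used was not called while another was. Probe sets with the suffix x_at can bind several transcripts, among them those used for CXCL2, CXCL8, KRT18, CA12, MDM2, DCN and ESR1. No coordinates are given, because the build used by the platform annotation was not matched to a reference.

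Arrays were grouped by their labels, and mimic was compared with control over all 6 arrays. Log2 values were fitted with limma 3.58.1 (lmFit and eBayes without trend, not robust) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. Differences are mimic minus control on the log2 scale, errors of differences are limma's moderated standard errors, and folds are 2 to the power of the difference. The 18 gene lists were fixed from general knowledge before the data were examined, as were the tests, most of the other settings and the rule for named genes. Lists were tested with limma's camera at an inter-gene correlation of 0.01, two-sided, adjusted over the 18 lists; camera was also run with an estimated correlation, and fry beside it. None of the 10 lists that camera called at the preset correlation passed with an estimated one. Members past the threshold were counted as adjusted over all probe sets and as adjusted over the list alone.

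By the rule for named genes, the text names the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap. It also names up to 4 members of each list past the threshold with the largest change, and 14 genes fixed in advance, of which those measured are given. BUB1, E2F1, TJP1, OAS1, CXCL11, HSD17B7 and DDIT4 were named after their values were seen, to complete small counts.

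The fit was tested on simulated data with 54613 probe sets, 200 of them changed. It recovered 67.0% of those changed by 0.5 and 97.0% of those changed by 1 on the log2 scale, and 4.7% of its calls were unchanged probe sets. With 18 simulated lists, the shifted one was found and 0 of the others were called. The simulation was not matched to the real lists, whose estimated correlations reached 0.672 for p53 target genes. Nor was it matched to the 13523 probe sets called in the data. It therefore cannot show how often camera calls unshifted lists of correlated genes. RNA integrity was checked from the 3' minus 5' log2 signal of the control probe sets of ACTB and GAPDH, with exact two-sided permutation tests. With 3 arrays against 3 such a test cannot give a p below 0.10. Of the 62 control probe sets, 0 passed the adjusted threshold in limma and 2 had an unadjusted p under 0.05.

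The other settings tried were leaving out the 40% dimmest probe sets, quantile normalization again, centring arrays on their medians, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array, averaging all probe sets of a gene, and stricter or unadjusted thresholds. Removing a loess trend of the change on the mean signal (span 0.3), and counting list members under every setting, were added after seeing the data. A planned test of genes with a seed site for miR-221 and miR-222 was not run, because 3' UTR sequences were not used here. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.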

Results

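MCF10A is an established, non-tumorigenic human mammary epithelial cell line. The cells were transfected with a mimic of the microRNAs miR-221 and miR-222, or with a control microRNA, called the mimic and the control below. MicroRNAs are short RNAs that pair with messenger RNAs and lower their level or translation, and miR-221 and miR-222 share the stretch that does most of this pairing. Total RNA of 3 biological replicates per group was hybridised to 6 single-colour arrays, and the values are log2 intensities per probe set. The array medians lay between 7.59 and 7.66. Across probe sets, pairs of arrays of the same group correlated with r from 0.9953 to 0.998, and pairs of arrays from different groups with r from 0.9821 to 0.9858; probe sets are not independent replicates. The number of arrays limits the precision.

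The comparison asked which transcripts differ between cells given the mimic and cells given the control. SLC38A4, an amino acid transporter, rose most, and CXCL1, a chemokine that attracts neutrophils, fell most. Genes of cell division and of cholesterol synthesis fell as groups, as did genes of epithelial junctions, while interferon response genes rose. These list calls were lost with an estimated correlation (adjusted p = 0.130 for cell cycle, 0.194 for cholesterol, 0.174 for epithelial and 0.284 for interferon genes with an estimated correlation). Reported targets of the microRNAs moved both ways: the cell cycle inhibitor gene CDKN1B fell and its relative CDKN1C rose. By limma with Benjamini-Hochberg adjustment, 6013 of 19775 genes (30.4%) changed, 2780 higher and 3233 lower in the mimic arrays. Of these, 190 were at least 2-fold higher and 414 at least 2-fold lower. The majority turned after quantile normalization of the values again (3418 genes higher, 3027 lower) and with array weights (3905 higher, 3715 lower). The 3 arrays of a group lay entirely on one side of the other 3 for 9013 genes (45.6%), where chance gives 10%. Counted by probe set, 13523 of 54613 (24.8%) changed, 6343 higher and 7180 lower. That majority also turned after quantile normalization (7109 higher, 6943 lower), with array weights (9576 and 8622), without mimic replicate 1 (6700 and 6614) and without control replicate 3 (6619 and 6614). With a 1.5-fold minimum added, 3590 probe sets passed.

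SLC38A4 averaged 9.47 ± 0.11 (SD, n = 3) in the mimic arrays and 4.51 ± 0.10 (SD, n = 3) in the control arrays, which is 31.1-fold higher. SPINK1, a trypsin inhibitor, averaged 11.92 ± 0.09 against 7.72 ± 0.01 (SD, n = 3 each), 18.3-fold higher. DCLK1, a microtubule-associated kinase, rose by 3.83 ± 0.13 on the log2 scale (SE). GREB1, a gene induced by oestrogen, rose by 3.02 ± 0.11 (SE), on 1 of its 3 probe sets. The cystine transporter subunit SLC7A11 rose by 2.77 ± 0.07 (SE), on all 3 of its probe sets. The other genes among the 12 largest rises were ZPLD1, CLGN, TMEM100, IYD, HOPX, AKAP12 and IGSF11, with log2 changes from 2.92 for ZPLD1 to 2.35 for IGSF11. All 12 had adjusted p-values (limma) of at most 1.8e-07, the value for CLGN, and the mimic arrays lay above the control arrays for each.

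CXCL1 averaged 8.60 ± 0.10 in the mimic arrays and 12.94 ± 0.20 in the control arrays (SD, n = 3 each), 20.2-fold higher in the control. RERG, a Ras-related growth inhibitor, averaged 7.02 ± 0.17 against 11.06 ± 0.13 (SD, n = 3 each), 16.4-fold higher in the control. The cytochrome P450 gene CYP4X1 had a log2 change of -3.61 ± 0.10 (SE), and NRP1, a co-receptor for semaphorins and vascular growth factors, one of -3.46 ± 0.08 (SE). NRP1 fell on 2 of its 4 probe sets, with a log2 change of -1.23 at the second. SHCBP1 fell by 3.20, and the chemokine gene CXCL2 fell by 3.02 on the log2 scale. Another CXCL2 probe set had a log2 change of -0.37, and a further one, at 0.10, did not pass. The other genes among the 12 largest falls were KIF14, DLGAP5, ANLN, PBK, and TOP2A and KIF20A of the cell cycle list, from -3.20 for KIF14 to -2.94 for PBK. The adjusted p-values (limma) of the 12 falls were at most 1.4e-08, the value for CXCL2, and the mimic arrays lay below the control arrays for each.

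**Figure D1:**
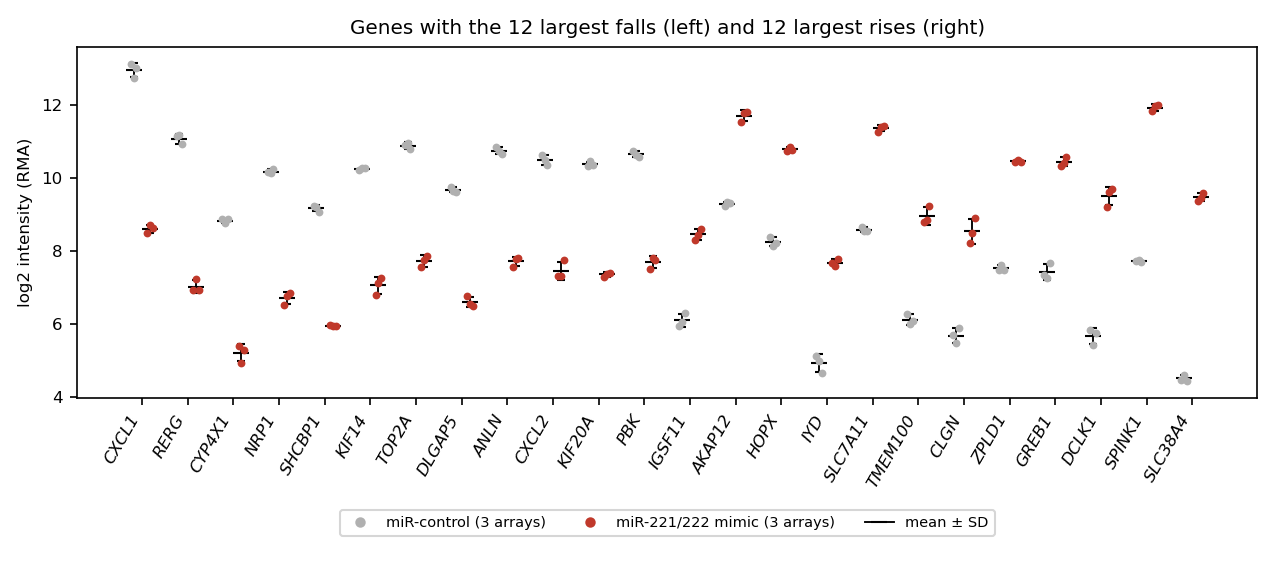
Log2 intensity of the genes with the 12 largest falls and the 12 largest rises, with 1 point per array (grey, 3 control arrays; red, 3 mimic arrays) and bars at the mean ± SD. The groups do not overlap for any of these genes, and SLC38A4 goes from a mean of 4.51 in the control to 9.47 in the mimic arrays.

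Among the 39 measured genes reported as targets of miR-221 or miR-222, 17 fell and 10 rose (17 and 11 adjusted over the list alone). TRPS1, a transcriptional repressor, fell most, by 1.26 on the log2 scale, on all 4 of its probe sets. The metalloproteinase inhibitor gene TIMP3 averaged 10.89 ± 0.06 against 11.77 ± 0.07 (SD, n = 3 each) and DICER1, which encodes the enzyme that cuts microRNA precursors, 10.06 ± 0.27 against 10.82 ± 0.01 (SD, n = 3 each). The other TIMP3 probe sets fell by less, with log2 changes of -0.42, -0.30 and -0.29. CDKN1B averaged 11.29 ± 0.11 against 11.94 ± 0.05 (SD, n = 3 each), 1.57-fold higher in the control. TCEAL1 (4.22-fold higher), the cytokine signalling inhibitor gene SOCS1 (4.08-fold higher), CDKN1C (2.54-fold higher) and the transcription factor gene FOXO3 (1.75-fold higher) rose; SOCS1 did so on 2 of its 4 probe sets. KIT, with a log2 change of 0.12 ± 0.06 (SE), and ESR1, with 0.14 ± 0.07 (SE), did not pass. KIT averaged 6.76 in the control arrays, below the array medians, and the ESR1 probe set used has the suffix x_at. Whether either target was expressed is not known. The ESR1 value was -0.01 with all its probe sets averaged, and 1 of its 9 probe sets fell, by 0.40 (adjusted p = 0.00172). The list as a whole was not called as shifted in 1 direction (median log2 change -0.06, camera adjusted p = 0.188). Falls and rises cancel in that test, so it does not show that the list is like other genes. Over all 19775 genes, 3233 fell and 2780 rose (30.4% changed). The target list was fixed from general knowledge, and its members without a measured value were not analysed here.

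**Figure D2:**
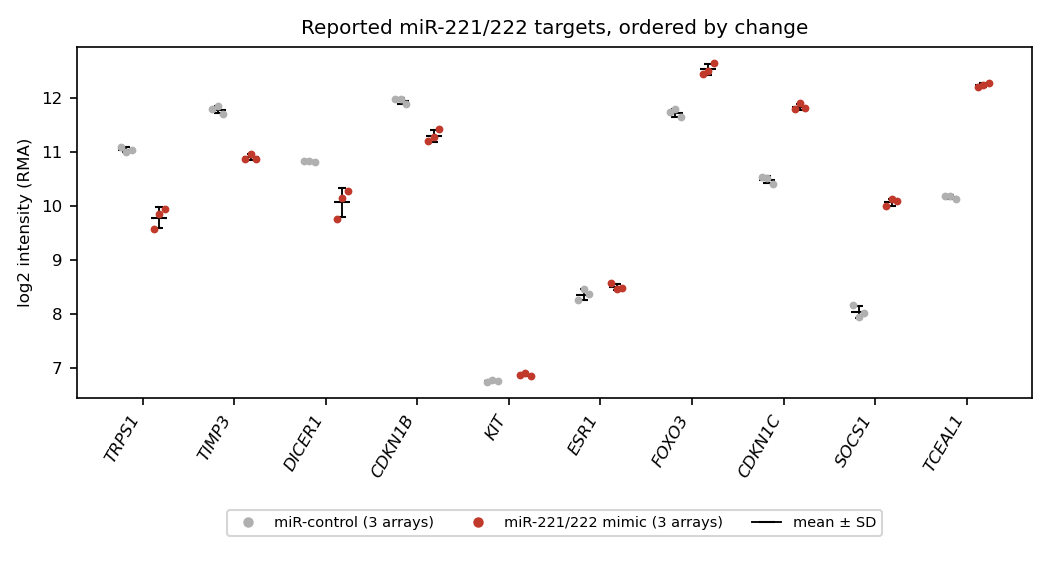
Log2 intensity of 10 reported targets of miR-221 and miR-222, ordered by change, with 1 point per array (grey, 3 control arrays; red, 3 mimic arrays) and bars at the mean ± SD. TRPS1, TIMP3, DICER1 and CDKN1B lie lower in the mimic arrays, and FOXO3, CDKN1C, SOCS1 and TCEAL1 lie higher.

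Of the 33 cell cycle genes, 31 fell and 0 rose, and the counts were the same adjusted over the list alone; 21 were at least 2-fold lower. TOP2A, a DNA topoisomerase of dividing cells, averaged 7.73 ± 0.15 in the mimic and 10.88 ± 0.08 in the control arrays (SD, n = 3 each). The mitotic kinesin gene KIF20A was 8.04-fold higher in the control, the mitotic kinase gene CDK1 7.03-fold and RRM2, a subunit of ribonucleotide reductase, 5.94-fold. BUB1 (log2 change -0.07) and E2F1 (-0.13) did not pass at the probe set used, although 2 of the 5 BUB1 probe sets fell. The median log2 change was -1.30 (camera adjusted p = 1.8e-29; adjusted p = 0.130 with an estimated correlation).

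Of the 14 measured cholesterol synthesis genes, 13 fell (14 adjusted over the list alone) and 0 rose. The examples were FDPS (2.44-fold higher in the control), the sterol sensor INSIG1 (2.39-fold), HMGCS1 (2.24-fold) and DHCR7 (2.22-fold). HSD17B7 had a log2 change of -0.21 ± 0.08 (SE) and did not pass over all probe sets. The median was -0.85 (camera adjusted p = 1.1e-12; adjusted p = 0.194 with an estimated correlation).

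Of the 30 epithelial junction and identity genes, 22 fell and 1 rose, with the same counts adjusted over the list alone. The adhesion protein gene EPCAM and the membrane transport gene MAL2 were each 2.91-fold higher in the control, the tight junction gene CLDN4 2.37-fold and the keratin gene KRT18 1.99-fold. CDH1, which encodes E-cadherin, averaged 11.45 ± 0.08 against 12.01 ± 0.02 (SD, n = 3 each). The member that rose was TJP1, a junction scaffold, by 0.55. The median was -0.48 (camera adjusted p = 6.5e-10; adjusted p = 0.174 with an estimated correlation).

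Mesenchymal and matrix genes moved both ways: 6 of 29 rose and 12 fell, also adjusted over the list alone. The intermediate filament gene VIM (1.63-fold higher) and the transcription factor gene ZEB2 (1.55-fold higher) rose, and ZEB1 had a log2 change of 0.16 ± 0.10 (SE), which did not pass. The matrix genes SPARC (3.86-fold higher in the control) and TNC (2.56-fold), the receptor kinase gene AXL (2.27-fold) and the smooth muscle gene TAGLN (2.21-fold) fell. TNC did so on 1 of its 3 probe sets and TAGLN on 2 of its 3, and the other AXL probe set had a log2 change of -0.26. The median was 0.05 and the mean -0.19, and the list was not called (camera adjusted p = 0.219, in the direction lower).

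Of 13 measured basal mammary genes, 7 fell and 4 rose (7 and 5 adjusted over the list alone). The keratin genes KRT14 (4.70-fold higher in the control) and KRT5 (3.31-fold), the desmosomal cadherin gene DSG3 (3.61-fold) and the integrin gene ITGB4 (2.35-fold) fell. The list's median was -0.56 (camera adjusted p = 0.0353; adjusted p = 0.580 with an estimated correlation), and the call was lost without mimic replicate 1 (adjusted p = 0.0628) and under 4 other settings, with adjusted p-values from 0.0534 to 0.116. With all probe sets of a gene averaged, the median was -0.18. Of 20 keratinocyte differentiation genes, 12 fell and 4 rose (13 and 4 adjusted over the list alone). The skin protease genes KLK5 (7.39-fold higher in the control) and KLK7 (5.66-fold) and the calcium-binding protein genes S100A8 (7.07-fold) and S100A9 (3.12-fold) fell. That list's median was -0.55 (camera adjusted p = 1.5e-05; adjusted p = 0.284 with an estimated correlation). Of 16 luminal and oestrogen receptor genes, 5 rose and 6 fell (6 and 6 adjusted over the list alone). The carbonic anhydrase gene CA12 (2.83-fold higher) and GREB1 rose, and the receptor gene ERBB3 (2.01-fold higher in the control) and KRT18 fell. The luminal median (0.08) and mean (0.12) lay above 0 and the test pointed lower, without a call (camera adjusted p = 0.973). Without control replicate 2, or without control replicate 3, 3 luminal genes rose.

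**Figure D3:**
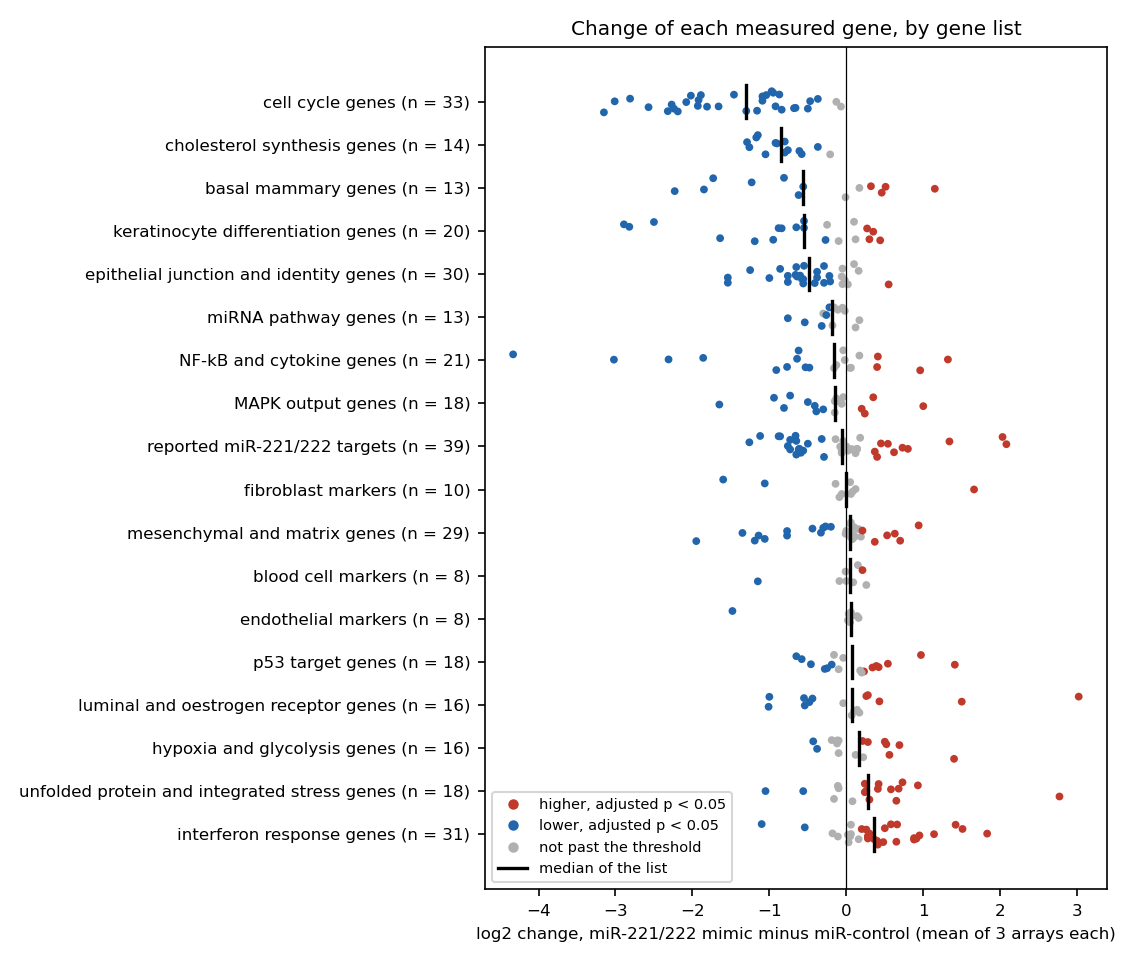
Log2 change (mimic minus control, means of 3 arrays each) of every measured gene of the 18 lists, with 1 point per gene, coloured by whether it passed as higher (red), as lower (blue) or did not pass (grey), and a black bar at each list's median. Cell cycle genes have the lowest median (-1.30), followed by cholesterol synthesis genes (-0.85), and interferon response genes have the highest (0.36).

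Of 31 measured interferon response genes, 21 rose and 2 fell (21 and 3 adjusted over the list alone). IFI27 (3.56-fold higher), IFI6 (2.85-fold), the ubiquitin-like modifier gene ISG15 (2.68-fold) and IFIT1 (2.21-fold) rose. The chemokine gene CXCL11 and the antiviral synthetase gene OAS1 fell, by 1.10 and 0.54. The median was 0.36 (camera adjusted p = 3.6e-06; adjusted p = 0.284 with an estimated correlation). Of 21 NF-kB and cytokine genes, 10 fell and 4 rose (10 and 5 adjusted over the list alone). CXCL8 (4.97-fold higher in the control) and CXCL3 (3.62-fold), neutrophil chemokine genes like CXCL1 and CXCL2, fell. The median was -0.16 (camera adjusted p = 0.00707; adjusted p = 0.174 with an estimated correlation), and -0.32 without the dimmest probe sets. CXCL1, CXCL2 and CXCL3 have similar sequences, and their separate levels are uncertain where probes bind more than 1 of them.

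Of 18 genes of the unfolded protein and integrated stress responses, 12 rose and 2 fell (12 and 3 adjusted over the list alone). SLC7A11, the asparagine synthetase gene ASNS (1.91-fold higher) and CHAC1 (1.66-fold higher), a glutathione-degrading enzyme, rose. The endoplasmic reticulum chaperone gene HYOU1 (2.07-fold higher in the control) and DDIT4, an inhibitor of mTORC1 signalling, fell. DDIT4 is also in the list of reported targets. The median was 0.28 (camera adjusted p = 0.00788; adjusted p = 0.580 with an estimated correlation). Of 18 MAPK output genes, 8 fell and 4 rose (10 and 4 adjusted over the list alone). The phosphatase genes DUSP6 (3.14-fold higher in the control) and DUSP4 (1.92-fold) and IER3 (1.75-fold) fell, and SPRY2, an inhibitor of receptor kinase signalling, rose from 10.35 ± 0.04 to 11.35 ± 0.12 (SD, n = 3 each). The median was -0.15 (camera adjusted p = 0.00868; adjusted p = 0.580 with an estimated correlation), and -0.08 after quantile normalization.

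Of 18 measured p53 target genes, 7 rose and 6 fell (9 and 7 adjusted over the list alone). TP53I3 (2.65-fold higher) and SESN1 (1.96-fold higher) rose, and MDM2, which encodes the ubiquitin ligase of p53, and TIGAR fell, by 0.65 and 0.58. MDM2 is also in the list of reported targets. The list was not called (median 0.07, camera adjusted p = 0.615), and its median was -0.05 with all probe sets of a gene averaged. Of 16 hypoxia and glycolysis genes, 7 rose and 2 fell, also adjusted over the list alone; 4 fell with eBayes trend and robust, and with all probe sets averaged. The collagen hydroxylase gene P4HA1 (2.63-fold higher), the histone demethylase gene KDM3A (1.62-fold), ANKRD37 (1.47-fold) and ADM (1.43-fold) rose, and the list was not called (median 0.17, camera adjusted p = 0.199). Of 13 microRNA pathway genes, 5 fell and 0 rose (7 and 0 adjusted over the list alone), among them DICER1, GEMIN4 (1.45-fold higher in the control), TARBP2 (1.25-fold) and PRKRA (1.20-fold). TARBP2 and PRKRA no longer passed with all their probe sets averaged, a setting under which 8 genes of the list fell; 1 rose after quantile normalization. The list's median was -0.18 (camera adjusted p = 0.0179; adjusted p = 0.580 with an estimated correlation), and the call was lost without the dimmest probe sets (adjusted p = 0.0532).

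Markers of other cell types were not called as lists. Of 10 fibroblast markers, 3 of which the mesenchymal list also holds, 1 rose and 2 fell, also adjusted over the list alone (median -0.01, camera adjusted p = 0.615); 1 fell without the dimmest probe sets. DCN, a matrix proteoglycan gene, was 3.16-fold higher, and FAP (3.04-fold higher in the control) and LUM (2.08-fold) fell. LUM averaged 4.09 in the mimic and 5.15 in the control arrays, near the lowest array values of 3.67 to 3.72. Its other probe set had a log2 change of -0.03 (limma adjusted p = 0.826). Of 8 endothelial markers, 1 fell and 0 rose, also adjusted over the list alone (median 0.06, camera adjusted p = 0.973): the receptor gene KDR, by 1.48. Of 8 measured blood cell markers, 1 rose and 1 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.973). CD14 fell by 1.15, and ITGAM rose by 0.21 (adjusted p = 0.0483), a call lost under 10 of its alternatives; 2 blood cell markers rose without the dimmest probe sets. The endothelial mean (-0.12) and the blood cell mean (-0.07) lay on the other side of 0 from their medians and tests.

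No detection calls were used, so whether a low value, such as the 4.51 of SLC38A4 in the control arrays, lies above background is not known.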

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

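Of the alternatives reported here, removing the intensity trend was chosen after seeing the data. Of 1282 values of the 92 named genes under alternatives, 1269 kept their direction and side of the threshold; the exceptions were ITGAM, TARBP2, PRKRA and ESR1 (-0.01 with all probe sets averaged). With a 1.5-fold minimum, 3590 probe sets passed (1346 higher, 2244 lower), by construction fewer; at an adjusted p under 0.01, 3828 were higher. With array weights 9576 were higher, and the cause was not tested. The planned array weights by restricted maximum likelihood stopped before converging, with a weight of 26.4 on mimic replicate 2 and 25428 probe sets called, so gene-by-gene weights were put in their place after that was seen. Without each array in turn, the changed probe sets ranged from 10266 to 13314 (higher 4451 to 6700, lower 5805 to 7241) and the changed genes from 4753 to 5868 (higher 2029 to 2913, lower 2670 to 3273). Replicate numbers did not pair the arrays: same-numbered deviations correlated at -0.11, 0.08 and 0.08. With the replicate number as a block, 13372 probe sets and 5812 genes were called, 5651 of these genes shared with the fit without it. Of the called genes 53.8% were lower, 47.0% after quantile normalization, 48.8% with array weights and 59.8% after median centring. All 10 list calls were lost in the form of camera that estimates the correlation. The form of the test does not enter the medians: cell cycle -1.30, cholesterol -0.85, basal -0.56, keratinocyte -0.55 and epithelial -0.48. The others were microRNA pathway -0.18, NF-kB -0.16, MAPK -0.15, stress 0.28 and interferon 0.36. Except for NF-kB genes, the estimates exceeded the preset 0.01, with 0.184 for cell cycle and 0.484 for cholesterol genes. The NF-kB estimate was -0.017, so a larger correlation did not end that call, although its unadjusted camera p rose from 0.00236 to 0.0291. The forms of camera therefore differ in more than the correlation, and a lost call does not by itself point to correlated genes. How much of each loss the correlation accounts for was not tested. With fry, which does not compare a list with other genes, the mesenchymal (fry adjusted p = 0.00652), luminal (0.0161), hypoxia (0.0130) and blood cell (0.0281) lists passed. Their medians were 0.05, 0.08, 0.17 and 0.05, and their means -0.19, 0.12, 0.19 and -0.07. The direction that fry gave is not reported here, and the medians do not show it. The basal call was lost without the dimmest probe sets (-0.56), after quantile normalization (-0.50), with array weights (-0.56), after removing the intensity trend (-0.50) and without mimic replicate 1 (-0.54, adjusted p = 0.0628); without each array its median ranged from -0.58 to -0.54, and with all probe sets averaged it was -0.18, still called (adjusted p = 0.0159). Among the other called lists, the NF-kB median was -0.32 without the dimmest probe sets and the MAPK median -0.08 after quantile normalization, both still called. The microRNA pathway call was lost without the dimmest probe sets (-0.18, adjusted p = 0.0532). The medians of uncalled lists changed sign for p53 targets with all probe sets averaged (-0.05) and for fibroblast markers without the dimmest probe sets (0.06), with all probe sets averaged (0.01) and without single arrays (-0.06 to 0.04). Where not stated, the cause was not tested. The planned seed site test and its alternatives were not run. Without detection calls, signal over background could not be judged, which limits what dim probe sets show.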

Other observations

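The gene families here were formed from symbols, and their tests were chosen after the list results had been seen, as were the tests of the 3 patterns and of neighbouring genes; only the comparison with other splits of the arrays was set beforehand. Of 343 families of at least 8 genes, 14 passed camera's adjusted threshold, 12 lower and 2 higher in the mimic arrays, and 53 had an unadjusted p under 0.05. With an estimated correlation 0 families passed (smallest adjusted p = 0.992). All 14 kept the sign of their median under both other scalings. Mitochondrial ribosomal protein genes were lower: 15 of 27 small-subunit (MRPS) and 26 of 50 large-subunit (MRPL) genes fell and 1 of each rose, with MRPS7 at -1.14 and MRPL19 at -0.74. Of 15 TIMM genes, which serve mitochondrial protein import, 9 fell and 1 rose (TIMM8B -0.83), and of 26 NUP genes, most of them for nuclear pore proteins, 13 fell and 1 rose (NUP88 -0.96). Of 11 proteasome PSMB genes 7 fell (PSMB5 -0.56).

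Metal-binding metallothionein (MT) genes had a median of -0.63, and 7 of 10 fell, among them MT1F (-0.90) and MT1X (-0.85); these near-identical copies share probe sequences, so their separate levels are uncertain. Of 13 genes with ITGB symbols 8 fell (ITGB8 -1.16), and of 14 kallikrein (KLK) genes 6 fell (KLK8 -1.94). Of 12 MCM symbols 8 fell, of 25 CDK symbols 9 fell and 1 rose (CDK6 -2.11), of 33 CDC symbols 15 fell and 4 rose, and of 12 PDCD symbols 6 fell. The cell cycle list also holds MCM, CDK and CDC genes, the keratinocyte list KLK genes and the basal list ITGB4. These families are therefore not findings separate from those lists. KLF transcription factor genes were higher, with 9 of 19 rising and 1 falling (KLF7 0.88, KLF4 0.80, KLF6 0.75), as were BBS genes of the primary cilium, with 5 of 8 rising and 0 falling (BBS10 1.26). The members named in these paragraphs were chosen after their values were seen.

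Cell cycle genes were lower in the mimic arrays. After a trend of the change with signal intensity was removed, their median was -1.34, which argues against that trend as the cause. The 3' minus 5' signal differed between groups by 0.04 for ACTB (0.36 ± 0.03 against 0.32 ± 0.04, SD, n = 3 each; exact permutation p = 0.30) and by 0.04 for GAPDH (0.03 ± 0.01 against -0.01 ± 0.04, SD, n = 3 each; exact permutation p = 0.10, the smallest possible, as the groups do not overlap). These p-values cannot show that the groups are alike; the size of the differences argues against RNA integrity as the whole cause, and a small difference in integrity stays open. Slower division of mimic cells is a candidate explanation that was not tested, and differences in culture density stay open.

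Of the reported targets, 10 rose in the mimic arrays, where pairing with the mimic would lower them. Of the 7 with several probe sets, all 7 had at least 2 higher and 0 had one lower, which argues against the choice of probe set. All 10 stayed higher under both other scalings. Those scalings moved the target list's median little, from -0.06 to -0.08 (quantile normalization) and -0.09 (median centring). The smallest of the 10 rises was 0.37 (GRB10), so this outcome could hardly have differed. Both scalings make the arrays alike again, so a change in total messenger RNA would stay hidden. Whether the scaling between arrays plays a part is therefore not decided. Indirect responses of the 10 rising targets may outweigh any direct effect, a hypothesis that would need the seed site test that was not run.

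The 77 mitochondrial ribosomal protein genes had a median of -0.23, with 41 lower and 2 higher. None of 10000 random lists matched on mean signal had an uncorrected median as low. This adds no support, because the MRPS and MRPL families were taken up for having the smallest camera p-values of the 343 families. Random lists also ignore correlation between genes. With an estimated correlation, the unadjusted camera p was 0.194 for MRPS and 0.316 for MRPL. After the intensity trend was removed the median of the 77 genes was -0.20. With all probe sets of each gene averaged it was -0.20 as well. Both values argue against these technical causes, and a link to slower growth is a hypothesis that was not tested.

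A clone with a gained or lost chromosome segment in one group was tested for through runs of neighbouring genes, and the test was run in 2 forms. The first used 382 runs of 50 genes of any signal: 0 passed (camera, smallest adjusted p = 0.146; 19 had an unadjusted p under 0.05), and the run medians lay between -0.07 and 0.13. After that result the test was repeated on 486 runs of 30 brighter genes, on the untested assumption that dim genes dilute a run. In this form 1 run passed (camera adjusted p = 0.0436) and 40 had an unadjusted p under 0.05, with medians between -0.23 and 0.21. In the run that passed, 15 members fell and 2 rose; 6 of those that fell are metallothionein genes and 9 are not, among them CPNE2 (-1.07) and ADGRG1 (-1.01). The forms differ in outcome, so a small segment stays open. Run length and gene signal changed together, so the difference cannot be put down to either.

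The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 13523 probe sets and 6013 genes, against at most 0 for the other splits, and 10 gene lists, against at most 7; 1 split, the real one, reached each of these values. Each other split mixes the groups 2 to 1 and keeps part of their difference. The rest of that difference enters the spread within the mixed groups, which holds down the calls however large the difference is. The 0 probe sets and genes called by the other splits were therefore to be expected and add no support.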
